A study of Mus musculus with 6 samples.

How the data were processed

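Gene expression was measured with 1-colour Affymetrix arrays in 6 samples of immortal mouse melanocytes, 3 of a line that is heterozygous for a Sox10 allele with a LacZ insertion and 3 of the wild-type line melan-Ink4a-Arf-1. The sample titles number the replicates and do not say whether they are separate cultures. Both lines lack Ink4a-Arf (Cdkn2a), and per the labels both were grown with 200 nM of a phorbol ester and 200 pM of cholera toxin. The heterozygous line came from mice of 3 days of age. RNA was labelled with biotin.

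The deposited values are on a log2 scale and, per the labels, were made by the authors with RMA, which corrects for background, normalises between arrays and gives 1 value per probe set. Partek is also named in the labels. The versions and settings of both, the role of Partek and the authors' own test are not given in the sources used here. The table held 41345 probe sets and 1 column for each array. The array medians lay between 5.72 and 5.79, no pair of arrays had identical values (0 pairs), and values were used without further scaling. An array gives signal over background and no counts, so its number of replicates limits the precision.

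Of the probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 were not listed with a gene. Of those with 1 symbol, 23328 had an Entrez identifier in the reference annotation of build GRCm38.p6, which gave chromosomes and positions, and 193 had none; 0 symbols differed. Where a gene had more than 1 probe set (1082 genes), the one with the highest mean over all 6 arrays was used, leaving 22180 genes. No filter on dim genes was applied.

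The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, 2-sided, 4 residual and 7.87 total degrees of freedom). Log2 differences are heterozygous minus wild type, with the standard error (SE) or the 95% confidence interval of that fit, and group means are given with the standard deviation (SD) of 3 arrays. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over all genes, and a 2-fold threshold (log2 difference of 1) was applied on top. No replicate block was used, because the labels give replicate numbers 1 to 3 in both lines without saying what a number shares, and the deviations of arrays with the same number did not correlate across genes (r of 0.007, 0.016 and −0.004).

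The 29 gene lists, the rule for the genes named, the tests and the alternatives were written before the data were examined, except where the text says otherwise. Lists were tested together with limma's camera at its preset correlation between genes of 0.01, which compares a list with all other genes. Camera with an estimated correlation and fry, which asks whether a list's genes move one way without comparing them with other genes, were alternatives. Counts of members are given over all genes and adjusted over the list alone. The lists cover melanin synthesis and melanosome proteins, pigment organelle biogenesis, neural crest and melanocyte lineage regulators, Schwann cell and myelin genes, lysosomal proteins, vacuolar ATPase subunits, cell division, p53 targets, interferon-stimulated genes, antigen presentation by MHC class I, extracellular matrix, cell adhesion, the Wnt, Notch, MAP kinase, and TGF-beta and BMP pathways, cholesterol synthesis, glycolysis, oxidative phosphorylation, unfolded protein and integrated stress responses, hypoxia, chemokines and cytokines, neural ion channels and transporters, ribosomal proteins, sex-linked genes, and markers of fibroblasts, keratinocytes, leukocytes, and endothelial and smooth muscle cells. Sox10 was in no list.

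The rule named Sox10, the 12 genes with the largest positive and the 12 with the largest negative difference among those that passed and whose arrays did not overlap between lines (unnamed gene models and sex-linked genes left out), and up to 4 passing members of each list by size of difference, or, where none passed, the 2 with the highest signal. Single values were tested with an exact 2-sided permutation test over the 20 regroupings of 6 arrays, whose smallest possible p is 0.1. Shares of genes were compared with Fisher's exact test, among others for the 50 genes on each side of Sox10. Chromosome medians used 14668 genes above the 40th percentile of all probe sets (called brighter genes here), with 10000 random gene sets of the same size for comparison and windows of 100 neighbouring genes in steps of 25.

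Alternatives were median centring, quantile normalization, dim genes left out, the mean of a gene's probe sets, every probe set counted, eBayes with trend or robust, no variance moderation, array weights, limma's treat, other thresholds, a replicate block and each array left out in turn. Counts without wild-type replicate 2, with X-linked and Y-linked genes left out and with chromosome 6 left out were added after the data were seen. Checks planned on Affymetrix control probe sets and on probe set suffixes were not run, since the table's identifiers are plain numbers.

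The gene test and camera were tried on simulated data in 10 runs with 200 changed genes each. Values were drawn independently for each gene, with the same spread in both lines and no array that stood apart. The gene test recovered 74.8% of genes changed by 0.58 (log2), 98.7% of those changed by 1 and 100% of those changed by 2, and 6.1% of its calls were unchanged genes. Camera passed an unshifted matrix list in 0 of 10 runs and one shifted by 0.3 in 10 of 10. These runs do not show how camera performs on lists of correlated genes, such as cell division (estimated correlation 0.751). Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.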

Results

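The data are 6 arrays of cultured mouse melanocytes, pigment-producing cells that derive from the neural crest. The Sox10 LacZ/+ line, called heterozygous here, and the Sox10 wild-type line melan-Ink4a-Arf-1 were each measured on 3 arrays. Array medians ranged from 5.72 to 5.79 on the log2 scale. Replicates of the heterozygous line lay closer to each other than those of the wild type, with a median SD per gene of 0.08 against 0.12. Wild-type replicate 2 stood apart: 261 genes differed at least 2-fold from the mean of the other wild-type arrays, against 22 and 54 for replicates 1 and 3 and at most 2 in the heterozygous line. The first principal component held 76.3% of the variance and separated the lines, and the second held 13.1% and set wild-type replicate 2 (−29.7) against replicates 1 (10.8) and 3 (16.9).

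The comparison asks which genes differ in expression when melanocytes carry 1 intact copy of Sox10, a transcription factor of neural crest and glial cells. Among the genes with the largest falls in the heterozygous line were the synaptic vesicle protein gene Syt4, the neuronal membrane protein gene Gpm6a and the glial connexin gene Gjc3. Among those with the largest rises were Acta2 (smooth muscle actin), Cald1 (the actin-binding protein caldesmon), Dcn (decorin) and Fbln5 (an elastic fibre protein). The key pigment enzyme gene Tyr was lower, at 8.65 ± 0.15 against 10.75 ± 0.19 in the wild type (mean ± SD, n = 3 each), while Tyrp1 and Pmel, abundant pigment genes, did not pass the test. Sox10 itself differed by −0.18 and did not pass the test.

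Of 22180 genes, 2967 (13.4%) passed, 1654 higher and 1313 lower in the heterozygous line, and 5533 had an unadjusted p below 0.05. At least 2-fold differences were found for 430 genes higher and 352 lower, and differences of 8-fold or more for 54 higher and 44 lower. The arrays of the lines did not overlap for 7013 genes (31.6%, where chance gives 10%), which include all 2967 that passed. Each genotype is represented by 1 cell line, so line and genotype cannot be told apart. The lines also differed in Xist and in Y-linked genes, so genotype cannot be told apart from a difference in sex either, and p-values measure only the spread between these arrays. Without wild-type replicate 2, 4222 genes passed (2308 higher, 1914 lower). With heterozygous replicate 1, 2 or 3 left out, 1817, 1780 and 1768 genes passed. The 2-fold count lay between 740 and 860 when any single array was left out.

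Among the 12 genes with the largest rise, Pde7b, which encodes a cAMP phosphodiesterase (Entrez 29863; chromosome 10, 20397052 to 20725078), went from 4.60 ± 0.26 to 11.05 ± 0.04, a log2 difference of 6.45 (SE 0.13, adjusted p 7.8e-08). Fbln5 rose by 6.11 (SE 0.13, adjusted p 1.29e-07) and Dcn by 5.92 (SE 0.08, adjusted p 2.05e-08). Prkg1, a cGMP-dependent protein kinase gene, rose by 5.56 and Acta2 by 5.34, from 7.11 ± 0.22 to 12.45 ± 0.04. Cald1, on chromosome 6, rose by 5.13. The remaining members were Ulbp1 (5.08), a ligand gene for an activating receptor of natural killer cells, the scaffold gene Iqgap2 (4.93), the receptor phosphatase gene Ptprk (4.63), the small GTPase gene Diras2 (4.60), Slc44a5 (4.30) and Man1a (4.30), a mannosidase gene of N-glycan processing. In 8 of these 12 genes, Pde7b and Dcn among them, the wild-type signal lay below the 40th percentile of all probe sets, so the size of the rise depends on the background of the array.

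The largest fall was that of Syt4 (Entrez 20983; chromosome 18, 31437808 to 31447415), from 12.11 ± 0.003 to 5.37 ± 0.34, a log2 difference of −6.74 (SE 0.16, adjusted p 1.53e-07). Elobl followed with −6.07, Gpm6a with −5.95 (SE 0.11, adjusted p 7.8e-08), Gjc3 with −5.93 (SE 0.10, adjusted p 4.09e-08), the annexin gene Anxa3 with −5.49 and the cation channel gene Mcoln3 with −5.42. Tecrl differed by −5.20, Atp10b by −5.11, Pcolce2, whose protein enhances procollagen processing, by −5.06 and Grem1, a BMP antagonist gene, by −4.75. Vsnl1, a neuronal calcium sensor gene, and Hebp2, a heme-binding protein gene, completed the 12 with −5.13 (SE 1.11, adjusted p 0.0192) and −4.44 (SE 0.75, adjusted p 0.0061). In both, wild-type replicate 2 was the low array; without it the differences were −6.67 and −5.48. Vsnl1 no longer passed when any other array was left out (adjusted p up to 0.0798; 5.05e-07 to 0.16 over all alternatives). The heterozygous signal was below the 40th percentile of all probe sets in 3 of the 12. Each of the other 23 genes named here passed with every single array left out.

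**Figure D1:**
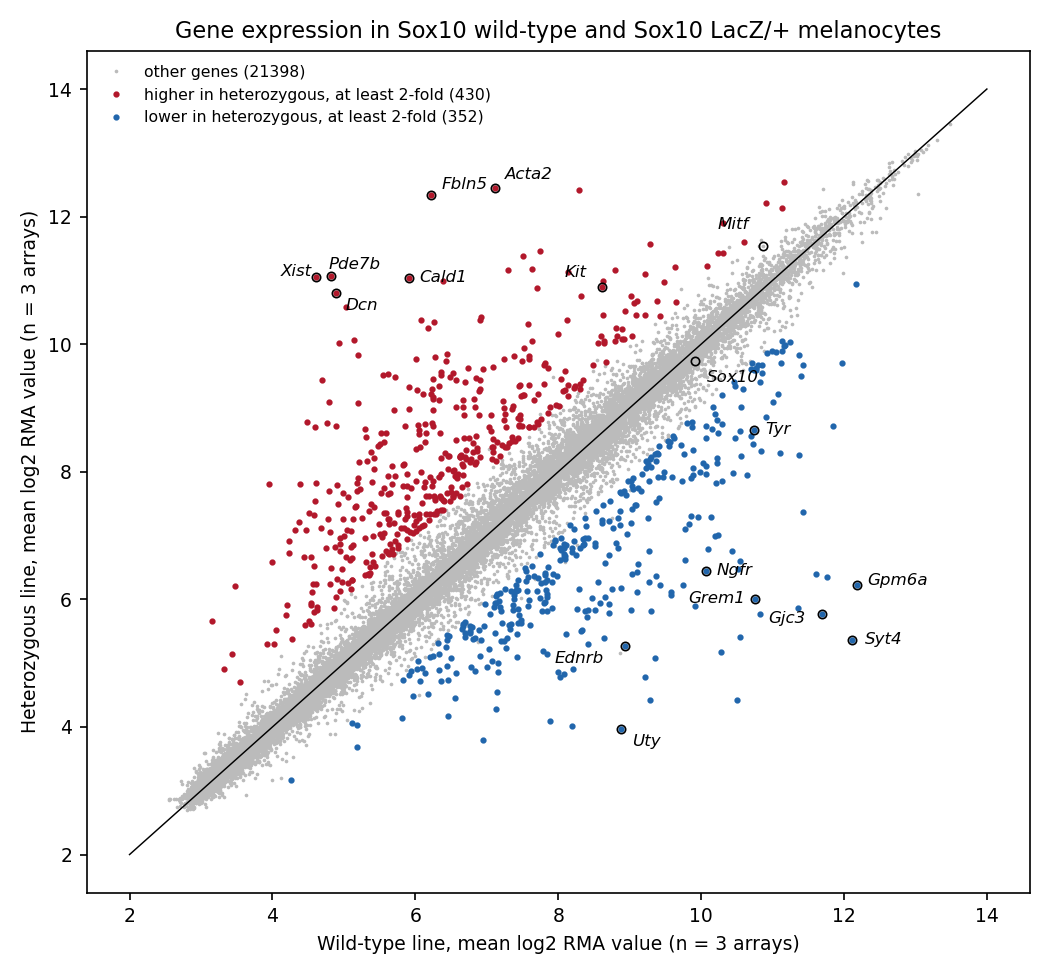
Mean log2 signal of each of 22180 genes in the wild-type line (x axis) and the heterozygous line (y axis), 3 arrays each. Red points are the 430 genes at least 2-fold higher and blue points the 352 at least 2-fold lower in the heterozygous line at an adjusted p below 0.05; Syt4 lies lowest relative to the diagonal, at 12.11 against 5.37.

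Sox10 (Entrez 20665; chromosome 15, 79154913 to 79164490) had a signal of 9.73 ± 0.05 in the heterozygous and 9.91 ± 0.10 in the wild-type line (n = 3 each), or 88.2% of wild type. The log2 difference was −0.18 (95% confidence interval −0.37 to 0.005, adjusted p 0.213; 0.0564 to 0.428 over the alternatives). The arrays of the lines did not overlap (exact permutation p 0.1, the smallest that 3 against 3 arrays allow). Sox10 was measured by 1 probe set, and which part of the transcript it covers is not given in the sources used here, so whether RNA from the LacZ allele adds to its signal is open. Cdkn2a, disrupted in both lines, had 7.07 ± 0.08 in the heterozygous and 7.16 ± 0.12 in the wild-type line, a difference of −0.09 (adjusted p 0.61), and which part of its transcript the probe set covers is not given either.

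Pigment genes moved in both directions. Of 21 measured genes for melanin synthesis and melanosome proteins, 4 rose, 7 fell and 10 did not pass. Tyr, which encodes the rate-limiting enzyme of melanin synthesis, differed by −2.10 (SE 0.12, adjusted p 1.28e-05) and Rab38, a small GTPase gene of melanosome transport, by −1.30 (SE 0.08). Mreg rose by 1.23 (SE 0.21) and Trpm1, a cation channel gene, by 1.14 (SE 0.19). Past 2-fold were 2 of those that rose and 3 of those that fell, including Gpr143, named after the results were seen. Among pigment genes singled out after their values were seen, Dct differed by −0.68 and passed, whereas Tyrp1 (−0.05, adjusted p 0.699), Pmel (0.22, adjusted p 0.219), Mlana (−0.29, adjusted p 0.0835) and Gpnmb (−0.13, adjusted p 0.36) did not. Melanin genes numbered 4 higher and 8 lower adjusted over the list alone; without wild-type replicate 2, 7 and 7. That array was higher than the other wild-type arrays in 16 of the 21 genes (median 0.26). The list as a whole had a median of −0.07 and did not pass (adjusted p 0.134), though it did without wild-type replicate 3 (0.0351; 0.0343 to 0.762 over all alternatives).

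Of 20 genes for the biogenesis of pigment organelles, Lyst rose (0.76, adjusted p 0.0382), Rabggta (−0.49, adjusted p 0.00423) and Hps5 (−0.44, adjusted p 0.0477) fell, and 17 did not pass. Organelle genes numbered 1 higher and 2 lower adjusted over the list alone, and without wild-type replicate 2, 1 and 3; the list did not pass (median −0.07, adjusted p 0.221). Lyst and Hps5 lost their calls when any array other than wild-type replicate 2 was left out (adjusted p up to 0.128 and 0.155; from 7.06e-05 and 0.00163 up to 0.194 and 0.174 over all alternatives), and 1 gene of this list passed without wild-type replicate 1 or 3 or heterozygous replicate 1 or 2. Among 38 lysosomal genes 5 rose, 7 fell and 26 did not pass. The rises included the protease gene Ctsk (2.30, SE 0.08) and the genes of the heparan and chondroitin sulfate degrading enzymes Sgsh (1.32, SE 0.09) and Arsb (0.79, SE 0.08); the largest fall was that of the protease gene Ctsh (−0.89, SE 0.12). Lysosomal genes numbered 6 higher and 11 lower adjusted over the list alone, as without wild-type replicate 2; 6 genes passed in total without heterozygous replicate 1 or 3 and 7 without heterozygous replicate 2. The lysosomal list did not pass (median −0.08, mean 0.02, camera downward, adjusted p 0.355).

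Of 16 vacuolar ATPase subunit genes, which encode the proton pump of acidic organelles, Atp6v1e1 on chromosome 6 rose (0.29, adjusted p 0.0326) and 15 did not pass. Adjusted over the list alone, 0 passed; without wild-type replicate 2, 3 were higher and 1 lower. Atp6v1e1 lost its call when any array other than wild-type replicate 2 was left out (adjusted p up to 0.132; 0.0101 to 0.132 over all alternatives), and 0 members passed without wild-type replicate 1 or any heterozygous array. The list had a median of −0.01 and a mean of 0.09 (camera downward, adjusted p 0.996).

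Regulators of the neural crest and melanocyte lineage moved in both directions. Of 27 measured, 6 rose, 5 fell and 16 did not pass. Ednrb, the endothelin receptor gene needed for melanocyte precursors, went from 8.94 ± 0.32 to 5.26 ± 0.19, a difference of −3.68 (SE 0.17, adjusted p 3.97e-06), and Ngfr, the low-affinity neurotrophin receptor gene, from 10.07 ± 0.14 to 6.45 ± 0.02, a difference of −3.61 (SE 0.09, adjusted p 1.67e-07). The transcription factor gene Sox6 differed by −2.67 (SE 0.15, adjusted p 1.07e-05). Kit, the receptor gene for stem cell factor, rose by 2.29 (SE 0.27, adjusted p 0.00092). On chromosome 6 lie 3 of the 6 that rose: Mitf, the master regulator gene of melanocytes (0.67), Met (0.53) and Sox5 (0.39), all of them singled out after their values were seen. Lineage regulators numbered 7 higher and 6 lower adjusted over the list alone, as without wild-type replicate 2. The list did not pass (median 0.05, mean −0.21, camera downward, adjusted p 0.996).

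Schwann cell and myelin genes were lower as a group. Of 22 measured, 9 fell, 1 rose (Pou3f2, 0.55, singled out after its value was seen) and 12 did not pass. Besides Gjc3, falls were found for Cadm4, an adhesion molecule gene of myelinating glia (−3.31, SE 0.11, adjusted p 6.63e-07), the calcium-binding protein gene S100b (−2.70, SE 0.14, adjusted p 7.04e-06) and the neural adhesion gene L1cam (−2.30, SE 0.19, adjusted p 0.00013). The median difference was −0.26 and the mean −0.90 (camera, adjusted p 3.71e-05). Wild-type replicate 2 was lower than the other wild-type arrays in this list (median −0.18), and the median difference was −0.31 without it. The call was lost at an adjusted p = 0.258 with an estimated correlation, the highest of its alternatives, which started at 1.59e-06. Glial genes numbered 1 higher and 10 lower adjusted over the list alone, and without wild-type replicate 2, 1 and 11; 6 members passed with any other single array left out.

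**Figure D2:**
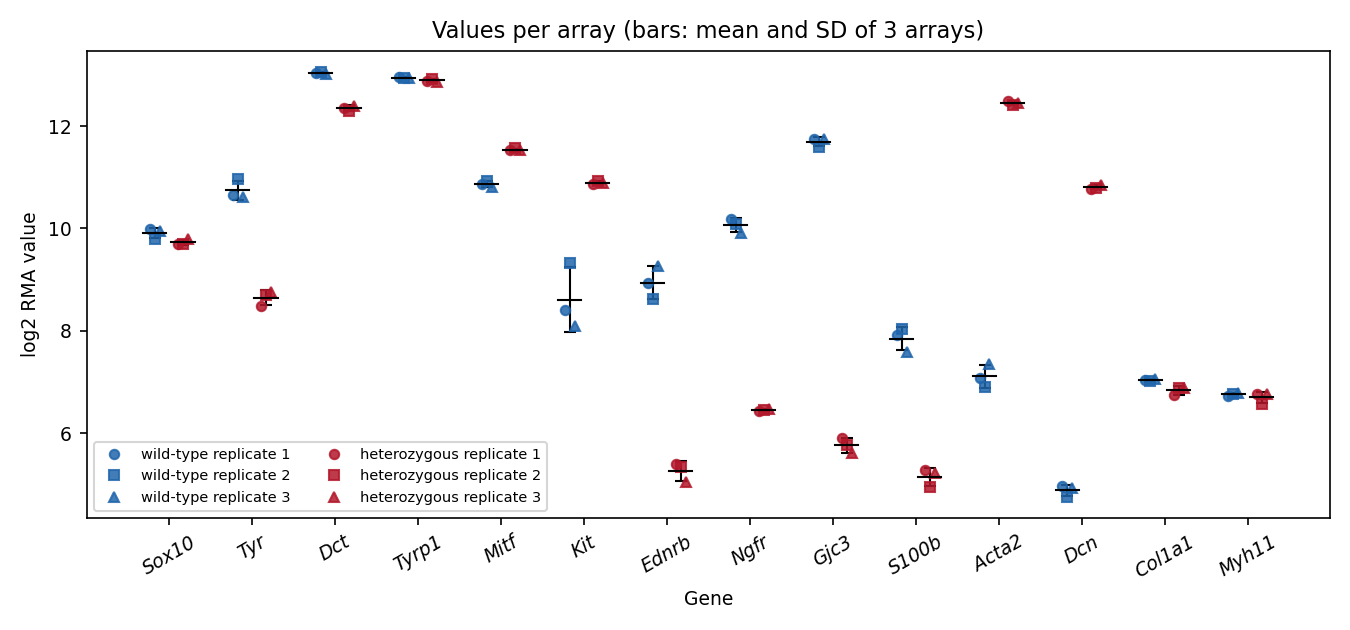
Log2 signal of 14 genes on each array of the wild-type and heterozygous lines, with the mean and SD of 3 arrays per line. Ednrb, Ngfr, Gjc3 and S100b lie lower and Kit, Acta2 and Dcn higher in the heterozygous line on every array, while Tyrp1 differs by −0.05.

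Genes of the TGF-beta and BMP list, which holds ligands and antagonists beside response genes, were higher as a group. Of 24 measured, 12 rose, 1 fell and 11 did not pass. The matricellular protein gene Ccn2 rose by 3.88 (SE 0.13, adjusted p 8.37e-07), the ligand gene Tgfb2 by 3.01 (SE 0.30, adjusted p 0.000351) and Acta2 by 5.34, whereas the antagonist gene Grem1 fell. The median was 0.31 and the mean 0.67 (camera, adjusted p 8.82e-05), with an adjusted p = 0.215 with an estimated correlation and a range of 3.26e-05 to 0.215 over all alternatives. Adjusted over the list alone, 12 were higher and 3 lower, as without wild-type replicate 2. Of 37 extracellular matrix genes 10 rose, 6 fell and 21 did not pass. Fbln5 and Dcn led the rises; Thbs2, a thrombospondin gene (−4.04, SE 0.12, adjusted p 3.45e-07), and Timp1, an inhibitor gene of matrix proteases (−3.47, SE 0.09, adjusted p 2.33e-07), led the falls. Matrix members counted 11 higher and 7 lower adjusted over the list alone, and 11 and 9 without wild-type replicate 2, which was lower than the other wild-type arrays in this list (median −0.18). Camera gave an adjusted p of 0.186 for the matrix list (median 0.04).

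Markers of other cell types were measured beside these genes. Of 15 fibroblast markers 4 rose and 11 did not pass: Dcn, the growth factor receptor gene Pdgfrb (4.08, SE 0.24), the fibulin gene Fbln1 (3.18, SE 0.08) and Col1a2 on chromosome 6 (1.24, SE 0.09). The median was 0.13 and the list passed (adjusted p 0.00259), with an adjusted p = 0.23 with an estimated correlation (8.5e-05 to 0.23 over all alternatives); adjusted over the list alone and without wild-type replicate 2, 5 were higher. Of 15 endothelial and smooth muscle markers 5 rose and 10 did not pass: Acta2, Eng, a co-receptor gene for TGF-beta ligands (1.01, SE 0.10), the actin-binding protein genes Tagln (0.94, SE 0.11) and Cnn1 (0.44, SE 0.08), and Vwf on chromosome 6, which was named after its value was seen. The median was 0.14 and the list passed (adjusted p 0.00374), with an adjusted p = 0.23 with an estimated correlation (0.000775 to 0.23 over all alternatives). Vascular markers numbered 6 higher adjusted over the list alone, and without wild-type replicate 2, 5; Cnn1 lost its call without heterozygous replicate 1 (adjusted p 0.0528; 0.00449 to 0.0528 over all alternatives). Acta2 and Tagln also belong to the TGF-beta and BMP list, and Dcn, Fbln1 and Col1a2 to the matrix list.

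Of 17 keratinocyte markers 0 passed by limma, and 1 higher and 3 lower had an unadjusted p below 0.05. Sfn differed by −0.06 and Cdh1 by 0.38 (adjusted p 0.0632; 0.0101 without wild-type replicate 2, and 0.0101 to 0.199 over all alternatives). Adjusted over the list alone, 0 passed; without wild-type replicate 2, 2 were higher, and without wild-type replicate 1, 1 passed (median −0.03, adjusted p 0.717). Of 15 leukocyte markers Cd68, a lysosomal membrane protein gene (1.32, SE 0.11), and Fcer1g (0.36, SE 0.09) rose and 13 did not pass. Leukocyte markers numbered 2 higher adjusted over the list alone; without wild-type replicate 2, 2 were higher and 1 lower (median −0.01, mean 0.05, camera downward, adjusted p 0.996). Fcer1g lost its call without wild-type replicate 1 or any heterozygous array, each of which left 1 gene (adjusted p up to 0.143; 0.0127 to 0.143 over all alternatives).

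Adhesion molecules changed in both directions, with 10 of 33 higher, 12 lower and 11 that did not pass. The rises included the cadherin gene Cdh6 (1.90, SE 0.19), the ephrin receptor gene Epha4 (1.64, SE 0.09), the plexin gene Plxnc1 (1.59, SE 0.25) and the integrin gene Itgb8 (1.57, SE 0.08). Adhesion genes numbered 12 higher and 13 lower adjusted over the list alone, and without wild-type replicate 2, 12 and 14; between 7 and 14 were lower with single arrays left out. The median was −0.02, the mean 0.05 and camera pointed downward (adjusted p 0.929). Of 27 Wnt pathway genes 7 rose, 3 fell and 17 did not pass. The receptor gene Fzd4 rose by 4.08 (SE 0.12, adjusted p 3.46e-07), Lgr5 by 2.03 (SE 0.13) and Znrf3, which limits Wnt receptors, by 1.54 (SE 0.14), while the secreted inhibitor gene Sfrp1 differed by −3.22 (SE 0.10, adjusted p 3.84e-07). Wnt genes numbered 9 higher and 3 lower adjusted over the list alone, and without wild-type replicate 2, 8 and 5. The Wnt list had a median of 0.08 and did not pass (adjusted p 0.0628), though it did without wild-type replicate 3 (0.0357; 0.00623 to 0.288 over all alternatives).

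Of 20 Notch pathway genes the ligand gene Jag1 rose by 3.15 (SE 0.15, adjusted p 5.31e-06), 3 fell and 16 did not pass. Lfng, which modifies Notch receptors, differed by −1.24 (SE 0.17), Notch1 by −0.38 (SE 0.07) and Notch2 by −0.37 (SE 0.08). Notch genes numbered 1 higher and 3 lower adjusted over the list alone, and without wild-type replicate 2, 2 and 3; the list did not pass (median −0.07, adjusted p 0.236). Notch2 lost its call when any array other than wild-type replicate 2 was left out (adjusted p up to 0.0905; from 0.00465 over all alternatives) and Notch1 without heterozygous replicate 3 (0.0611; 0.00448 to 0.0611), which left 2 members past the test. Of 25 MAP kinase feedback and immediate early genes 9 rose, 2 fell and 14 did not pass. The phosphatase genes Dusp1 (0.98, SE 0.09) and Dusp4 (0.83, SE 0.19), the transcription factor gene Etv1 (0.83, SE 0.09) and the pathway inhibitor gene Spry1 (0.70, SE 0.18) rose. The MAP kinase list had a median of 0.17 and did not pass (adjusted p 0.0555), but passed without wild-type replicate 1 (0.0483) or 2 (0.00913), with a range of 0.00913 to 0.288 over all alternatives. Its members counted 10 higher and 4 lower adjusted over the list alone, and 11 and 2 without wild-type replicate 2; in total 6 passed without wild-type replicate 1 or heterozygous replicate 1, 4 without heterozygous replicate 2 and 5 without heterozygous replicate 3. Dusp4 lost its call when any array other than wild-type replicate 2 was left out (adjusted p up to 0.0896; 0.000245 to 0.151 over all alternatives), and Spry1 without wild-type replicate 1 or any heterozygous array (up to 0.135; 0.0046 to 0.199).

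Antigen presentation genes of MHC class I were lower as a group, with 4 of 12 that fell and 8 that did not pass. H2-K1 differed by −1.99 (SE 0.12, adjusted p 2.07e-05), H2-Q4 by −1.29 (SE 0.18, adjusted p 0.00206), and the peptide transporter genes Tap2 by −0.61 (SE 0.13) and Tap1 by −0.44 (SE 0.10). All 4 lie close together on chromosome 17, between positions 33996012 and 35384674, so they are not independent of each other. The brighter genes of the whole chromosome had a median of −0.03, and a cause tied to this stretch was not tested. The median was −0.31 (camera, adjusted p 0.0091), with an adjusted p = 0.459 with an estimated correlation (0.00432 to 0.459 over all alternatives). The array of wild-type replicate 2 was lower than the other wild-type arrays here as well (median −0.15), and without it the median difference was −0.33. Adjusted over the list alone 6 were lower, and without wild-type replicate 2, 5. Without wild-type replicate 1 or 3 or heterozygous replicate 2 or 3, 2 members passed; Tap1 and Tap2 were the genes lost (adjusted p up to 0.0833 and 0.0813; from 0.012 to 0.0914 and from 0.000699 to 0.126 over all alternatives).

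Of 26 interferon-stimulated genes 4 rose, 2 fell and 20 did not pass. The chemokine gene Cxcl10 differed by −2.58 (SE 0.18), while the antiviral genes Oasl2 (1.19, SE 0.15), Rtp4 (1.06, SE 0.11) and Bst2 (0.92, SE 0.11) rose. Interferon genes numbered 5 higher and 2 lower adjusted over the list alone, and without wild-type replicate 2, 3 and 4; that array was lower than the other wild-type arrays in this list (median −0.27). The interferon list did not pass (median −0.01, adjusted p 0.996); without wild-type replicate 2 the median was −0.19 and the adjusted p 0.286 (0.286 to 0.997 over all alternatives), and without wild-type replicate 1 or 3 the median was 0.04 or 0.09. Of 24 chemokine and cytokine genes 6 rose, 1 fell and 17 did not pass, with Il6 (2.60, SE 0.12), Il33 (1.43, SE 0.23), Ccl2 (1.20, SE 0.15) and Cx3cl1 (1.07, SE 0.13) leading the rises. Cytokine members counted 6 higher and 1 lower adjusted over the list alone and 6 and 2 without wild-type replicate 2; the list did not pass (median 0.06, adjusted p 0.159).

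Cell division genes had a slightly higher median in the heterozygous line, by no more than wild-type replicate 2 differed from the other wild-type arrays. The size of the count rested on that array. Of 38 measured, 3 replication genes rose, Mcm2 on chromosome 6 (0.87, adjusted p 0.0351), Cdt1 (0.58, adjusted p 0.0472) and Cdc6 (0.54, adjusted p 0.0139), and 35 did not pass. The median was 0.17 (camera, adjusted p 0.00165), with an adjusted p = 0.751 with an estimated correlation (2.5e-08 to 0.751 over all alternatives). Fry gave an adjusted p of 0.255 for this list. The median difference was 0.26 without wild-type replicate 2. Adjusted over the list alone 1 was higher. Without wild-type replicate 2, which was higher than the other wild-type arrays in all 38 genes (median 0.30), 22 were higher; 1 passed without wild-type replicate 1 or 3 or heterozygous replicate 1, and 0 without heterozygous replicate 2 or 3. Mcm2 and Cdt1 lost their calls when any array other than wild-type replicate 2 was left out (adjusted p up to 0.128 and 0.158; from 9.89e-05 to 0.191 and from 0.00069 to 0.201 over all alternatives), and Cdc6 without heterozygous replicate 2 or 3 (up to 0.0646; 0.00239 to 0.0912).

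Ribosomal protein genes were also slightly higher as a group. Of 41 measured, 5 rose, among them Rpl3 (0.49, SE 0.13), Rpl30 (0.44, SE 0.10), Rps7 (0.42, SE 0.09) and Rps14 (0.39, SE 0.09), and 36 did not pass. The median was 0.16 (camera, adjusted p 0.000203), with an adjusted p = 0.369 with an estimated correlation (3.56e-05 to 0.369 over all alternatives). On wild-type replicate 2 this list was higher than on the other wild-type arrays (median 0.07), and the median difference was 0.21 without it. Ribosomal genes numbered 5 higher adjusted over the list alone, and without wild-type replicate 2, 9. The count was 2 without wild-type replicate 3, 1 without heterozygous replicate 1 or 2 and 0 without heterozygous replicate 3. Over all single arrays left out, the limma adjusted p-values reached 0.158 (Rpl3), 0.0997 (Rpl30), 0.0687 (Rps7) and 0.116 (Rps14).

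Of 18 p53 target genes 2 rose, 4 fell and 12 did not pass. The death receptor gene Tnfrsf10b differed by −1.96 (SE 0.11, adjusted p 1.22e-05), the cell cycle inhibitor gene Cdkn1a by −0.89 (SE 0.07, adjusted p 9.95e-05), Eda2r by −0.78 (SE 0.11) and Phlda3 by −0.42 (SE 0.10). Targets of p53 numbered 2 higher and 4 lower adjusted over the list alone, and without wild-type replicate 2, 2 and 5. The p53 list had a median of 0.02 (−0.10 without wild-type replicate 2, and also negative without wild-type replicate 3 or heterozygous replicate 1) and a mean of −0.17 (camera downward, adjusted p 0.19); 3 members passed without wild-type replicate 1 or any heterozygous array. Phlda3 lost its call when any array other than wild-type replicate 2 was left out (adjusted p up to 0.127; from 0.00433 over all alternatives). Of 25 genes of the unfolded protein and integrated stress responses 2 rose, 3 fell and 20 did not pass. The serine synthesis gene Phgdh rose by 0.95 (SE 0.09) and Shmt2 by 0.42 (SE 0.10), and Atf3 (−0.88, SE 0.21) and the chaperone gene Dnajb9 (−0.51, SE 0.13) fell. The stress list counted 2 higher and 4 lower adjusted over the list alone and 3 and 3 without wild-type replicate 2, and did not pass (median −0.04, adjusted p 0.283). With wild-type replicate 1 or any heterozygous array left out 1 stress gene passed, and without wild-type replicate 3, 2; the highest adjusted p-values were 0.104 for Atf3, 0.134 for Dnajb9 and 0.113 for Shmt2.

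Metabolic genes changed singly. Of 17 glycolysis genes the phosphofructokinase gene Pfkm rose (0.54, SE 0.11), Aldoc (−2.04, SE 0.12, adjusted p 1.29e-05), Eno2 on chromosome 6 (−0.75, SE 0.17) and the lactate exporter gene Slc16a3 (−0.68, SE 0.16) fell, and 13 did not pass. Glycolysis genes numbered 1 higher and 3 lower adjusted over the list alone, and without wild-type replicate 2, which was higher than the other wild-type arrays in 15 of 17 genes (median 0.32), 4 and 3. The glycolysis list did not pass (median −0.03, adjusted p 0.306), but did without wild-type replicate 3 (median −0.11, 0.0351); without wild-type replicate 2 the median was 0.05 and the adjusted p 0.772 (0.0351 to 0.87 over all alternatives). In total 2 glycolysis genes passed without wild-type replicate 1 or heterozygous replicate 2 or 3 and 1 without heterozygous replicate 1; Eno2, Slc16a3 and Pfkm reached adjusted p-values of 0.0873, 0.105 and 0.0703 there. Of 32 genes of oxidative phosphorylation 3 rose and 29 did not pass: Ppargc1a, a coactivator gene of mitochondrial biogenesis (2.71, SE 0.29, adjusted p 0.000567), and, on chromosome 6, Ndufa4 (0.44, SE 0.08) and Ndufa9 (0.41, SE 0.09). Respiratory genes numbered 3 higher adjusted over the list alone, and without wild-type replicate 2, 4. This list had a median of 0.08 and did not pass (adjusted p 0.0555), but did without wild-type replicate 1 (0.0268) or 2 (0.0234) or heterozygous replicate 1 (0.0482; 0.0234 to 0.677 over all alternatives). Ndufa9 lost its call without wild-type replicate 1 or any heterozygous array (adjusted p up to 0.103; 0.00929 to 0.103).

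Of 17 hypoxia response genes 2 rose, 2 fell and 13 did not pass. The peptide hormone gene Adm differed by −2.30 (SE 0.37) and Car9, a carbonic anhydrase gene, by −0.45 (SE 0.11), while Egln3, an oxygen sensor gene (1.26, SE 0.13), and the prolyl hydroxylase gene P4ha2 (0.998, SE 0.26) rose. Wild-type replicate 2 was higher than the other wild-type arrays in 16 of the 17 genes (median 0.71). Hypoxia genes numbered 2 higher and 5 lower adjusted over the list alone, and without wild-type replicate 2, 3 and 2. The hypoxia list had a median of −0.24 and did not pass (adjusted p 0.159), but did without wild-type replicate 3 (0.0129); without wild-type replicate 2 the median was −0.01 and the adjusted p 0.962 (0.0129 to 0.962 over all alternatives). P4ha2 lost its call when any array other than wild-type replicate 2 was left out (adjusted p up to 0.144; 7.92e-05 to 0.211 over all alternatives), Car9 when any other than wild-type replicate 3 was (up to 0.104; 0.00284 to 0.132), and 2 genes passed without wild-type replicate 1 or any heterozygous array.

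Of 19 cholesterol synthesis genes Insig1 rose (0.42, SE 0.08), Stard4 fell (−0.37, SE 0.07) and 17 did not pass. Cholesterol genes numbered 1 higher and 1 lower adjusted over the list alone, and without wild-type replicate 2, 2 and 4. The cholesterol list did not pass (median −0.12, adjusted p 0.306); Insig1 lost its call without heterozygous replicate 3 (adjusted p 0.0563; 0.00203 to 0.0563 over all alternatives) and Stard4 without heterozygous replicate 1 (0.0684; 0.00791 to 0.0684), and either left 1 gene. Of 23 ion channel and transporter genes of neural cells 4 rose, 3 fell and 16 did not pass. The glutamate receptor gene Gria4 (1.58, SE 0.38), the transporter gene Slc6a17 (0.91, SE 0.24) and the calcium channel gene Cacna1c on chromosome 6 (0.41, SE 0.10) rose, and the cation channel gene Trpv2 fell (−0.95, SE 0.19). Neural channel members counted 4 higher and 5 lower adjusted over the list alone and 4 and 4 without wild-type replicate 2; the list did not pass (median −0.02, and 0.01 without wild-type replicate 2 or in either scaling; adjusted p 0.58). None of these 4 genes kept its call throughout (adjusted p up to 0.102 for Gria4, 0.142 for Slc6a17, 0.113 for Cacna1c and 0.0535 for Trpv2 with single arrays left out): 0 members of the list passed without heterozygous replicate 1 or 2, 2 without heterozygous replicate 3, 3 without wild-type replicate 1 and 4 without wild-type replicate 3.

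**Figure D3:**
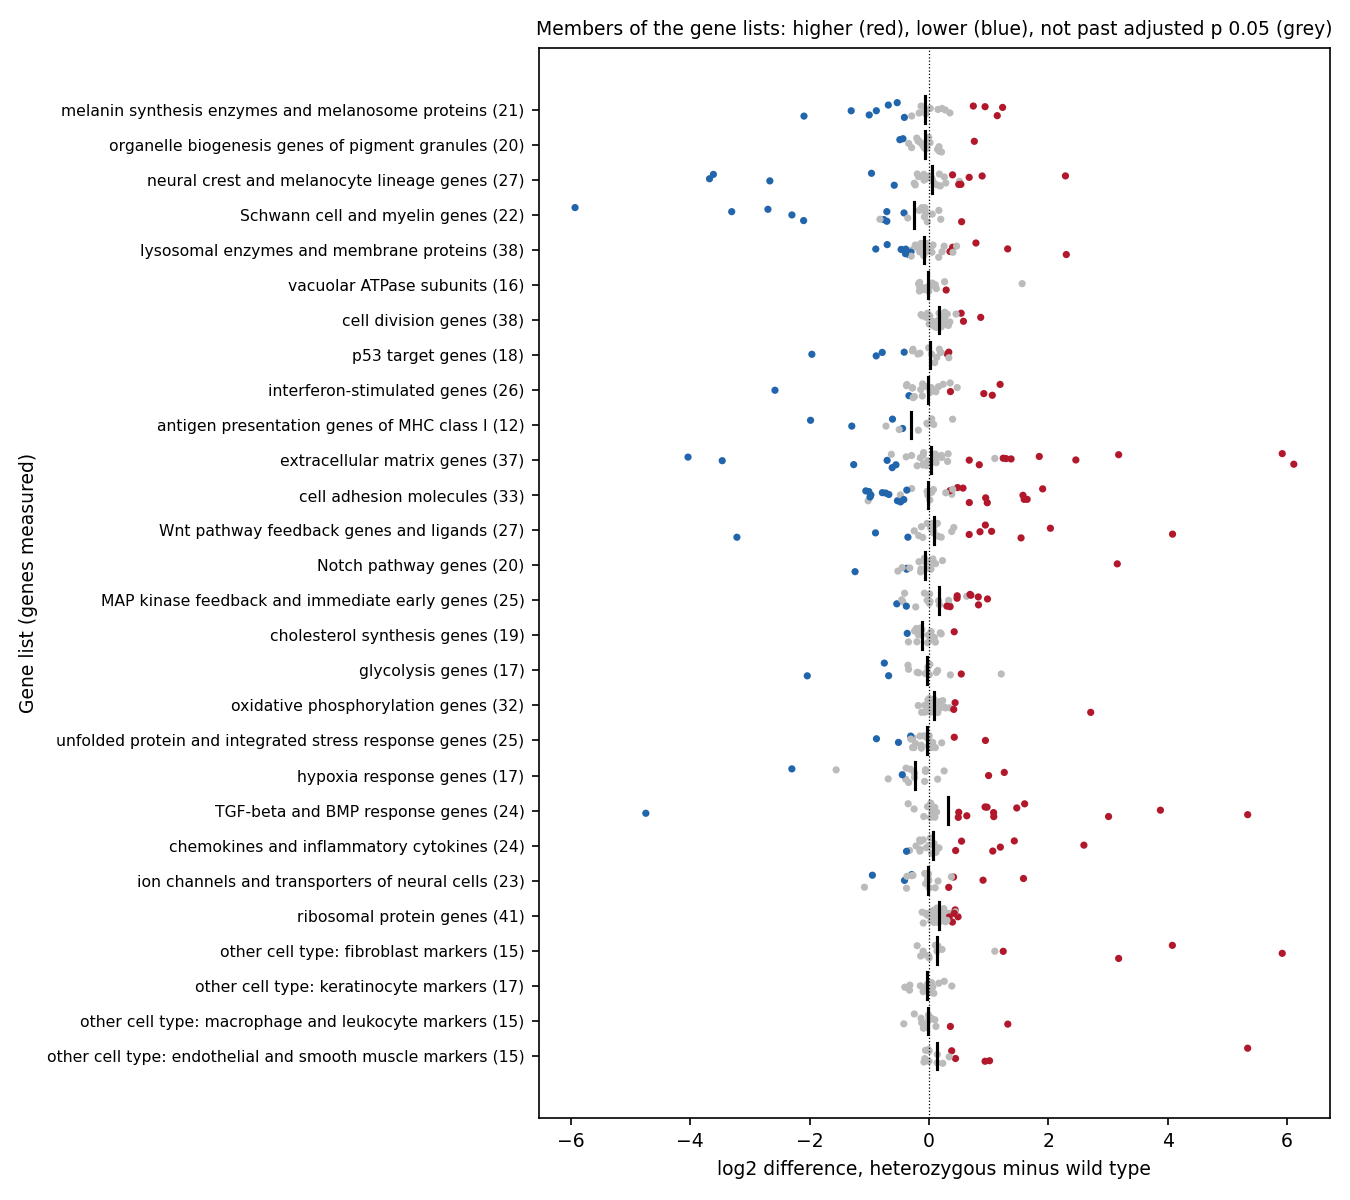
Log2 differences (heterozygous minus wild type) of the measured members of 28 gene lists, 1 point per gene, with a black tick at the median of each list. The TGF-beta and BMP list has a median of 0.31 and the Schwann cell and myelin list of −0.26.

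The lines differed in sex-linked genes. Xist, the RNA gene of X inactivation, had 11.06 ± 0.04 in the heterozygous and 4.81 ± 0.07 in the wild-type line, a difference of 6.25 (SE 0.07). The Y-linked genes Uty (−4.92, SE 0.13), Eif2s3y (−4.86, SE 0.17) and Kdm5d (−4.18, SE 0.09) were lower in the heterozygous line, so that of 4 measured members 1 rose and 3 fell, also adjusted over the list alone and without wild-type replicate 2. Each gave an exact permutation p of 0.1, the smallest possible with 3 arrays per line. The sex-linked list passed (median −4.52, adjusted p 0.00587), with an adjusted p = 0.23 with an estimated correlation (0.00243 to 0.23 over all alternatives). Its direction follows from holding 3 Y-linked genes beside Xist, which moved the opposite way, so the list test adds nothing to the single genes. Among X-linked genes 114 of 899 passed (12.7%; 55 higher, 59 lower) against 2831 of 21065 autosomal genes (13.4%), an odds ratio of 0.935 (95% confidence interval 0.759 to 1.145, Fisher's exact p 0.549).

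Of the 100 genes nearest to Sox10, 50 on each side, 8 rose and 3 fell, or 11% against 13.4% elsewhere (odds ratio 0.80, 95% confidence interval 0.385 to 1.503, Fisher's exact p 0.558). Of the 25 nearest on each side 4 rose and 3 fell, an odds ratio of 1.05 (0.40 to 2.367, Fisher's exact p 0.836). The rises included Apobec3, an antiviral deaminase gene (2.77, SE 0.26), and C1qtnf6 (1.34, SE 0.13), both singled out after their values were seen.

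Genes on chromosome 6 were higher as a set in the heterozygous line. The median difference of its 710 brighter genes was 0.24, where random gene sets of that size gave −0.02 to 0.04 and the other autosomes −0.03 to 0.03. Chromosome 17 also lay outside the range of its random gene sets, at −0.03 against −0.02 to 0.04, with 36 of its 729 brighter genes called higher and 61 lower. Of the brighter genes of chromosome 6, 74.1% were higher, against 50.5% on the other autosomes. On the whole chromosome 247 genes rose and 35 fell, which is 14.9% of all genes that rose. The median was 0.29 and 0.28 against wild-type replicates 1 and 3 and 0.12 against wild-type replicate 2. Mitf, Met, Mcm2 and Braf, a MAP kinase pathway gene (0.45, adjusted p 0.0328, named after its value was seen), are among those that rose.

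**Figure D4:**
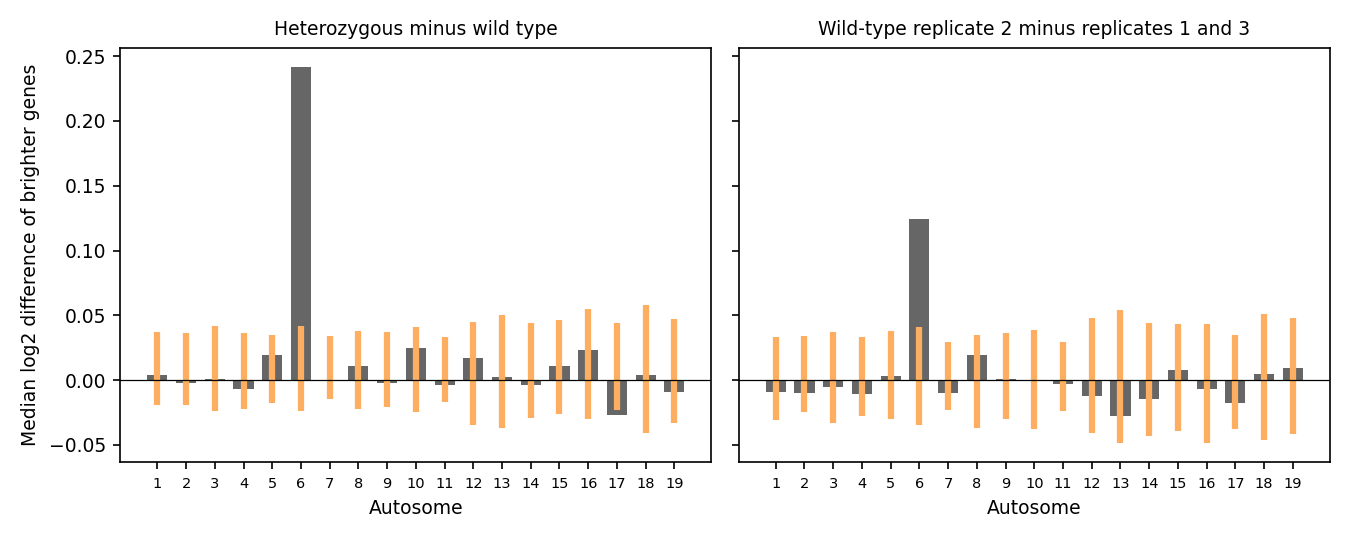
Median log2 difference of the brighter genes of each autosome, between the heterozygous and wild-type lines and between wild-type replicate 2 and wild-type replicates 1 and 3; orange lines give the range of 10000 random gene sets. Chromosome 6 stands out in both, at 0.24 and 0.12.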

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

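The choice of the 4 probe sets named here was made only after their values were seen. The 17824 probe sets without a single gene name take no part in the comparison of genes. Tested in the same way, 53 of them were at least 2-fold higher and 71 at least 2-fold lower in the heterozygous line, a signal in data outside the comparison. The largest differences were 6.55 for probe set 17550478 (5.42 in the wild type and 11.97 in the heterozygous line), 6.31 for 17550444, −5.65 for 17290093 (11.33 and 5.68) and −4.93 for 17549296. No explanation was tested for them.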

How the results depend on the processing

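Counts with X-linked and Y-linked genes left out, with chromosome 6 left out and without wild-type replicate 2 were added after the results were seen. The last was also part of the planned leave-one-out. No result past the threshold changed direction in the alternatives run. Below it, Sfn (−0.21 to 0.09 with single arrays left out), the direction of 8 list tests, and the sign of the median of 8 lists with 1 array left out or in another scaling, did. Of the gene counts 99 stayed within 1.5 times the value given and 18 moved; list tests kept their side of the threshold in 432 cases, gained a call in 23 and lost one in 9; Sox10 kept its in 15 of 15 and the neighbours of Sox10 theirs in 2. For the other named genes 1633 values kept their call, 179 lost it and 3 gained one. Of 119 named genes past the threshold, 84 stayed past it with every single array left out and 35 did not. Of the 782 genes past 2-fold, at least 738 were called in the same direction in each scaling, probe set, prior, weight, block and leave-one-out setting that tests all of them, except for 607 without variance moderation.

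Without variance moderation 1717 genes passed (1009 higher, 708 lower). At an adjusted p below 0.01, 1588 passed (888 and 700), and at 1.5-fold 1536 did in place of 782 (830 and 706), both by construction. With single arrays left out the count ran from 1768 to 4222 (979 to 2308 higher, 779 to 1914 lower), the highest without wild-type replicate 2. A replicate block gave 2512. With X-linked and Y-linked genes left out, and genes without a known chromosome kept, 2854 passed. With chromosome 6 left out 2650 passed (1391 and 1259). Median centring put the median of all genes at 0.0303 and raised the share of calls that were higher to 60.8%.

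Among lists, none of the 8 calls held when camera was run with an estimated correlation: adjusted p was 0.258 for Schwann cell and myelin genes, 0.751 for cell division, 0.459 for MHC class I, 0.215 for TGF-beta and BMP, 0.369 for ribosomal proteins, and 0.23 for fibroblast, for endothelial and smooth muscle, and for sex-linked genes. At the preset correlation these calls held with each single array left out. The estimate was −0.007 for TGF-beta and BMP, −0.002 for fibroblast and −0.075 for sex-linked genes, below the preset 0.01. A higher correlation between genes was therefore not what ended the calls of these lists. With an estimated correlation camera is also limited to the 4 residual degrees of freedom, which by itself raises p-values. A call lost there thus does not single out correlation between genes, and the parts were not tested apart. Fry, which does not compare a list with other genes, gave 0.255 for cell division and passed melanin synthesis (0.0343), organelle biogenesis (0.0326), neural crest (0.00533), p53 targets (0.0158), matrix (0.00533), Wnt (0.00623), MAP kinase (0.0132), oxidative phosphorylation (0.0343) and chemokines (0.0321). MAP kinase genes also passed with the mean of probe sets (0.0345), array weights (0.0405) and chromosome 6 left out (0.0418), Wnt genes with chromosome 6 left out (0.0472) and oxidative phosphorylation with an eBayes trend (0.0355). With single arrays left out, adjusted p ran from 0.00913 to 0.145 for MAP kinase, 0.0234 to 0.165 for oxidative phosphorylation, 0.0351 to 0.762 for melanin synthesis, 0.0357 to 0.108 for Wnt, 0.0351 to 0.772 for glycolysis and 0.0129 to 0.962 for hypoxia. For these list results the cause was not tested.

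The 3-prime to 5-prime check of RNA quality, its Gapdh and beta-actin variant, the filter on probe set suffixes, and list tests under robust eBayes or without moderation were not run. Signal over background limits dim genes, whose differences an array compresses, and 3 arrays per line limit small ones.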

Other observations

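The family test and the genes named in the first 2 paragraphs, and the tests on local regulation of chromosome 6, on fibroblasts, on smooth muscle cells, on the 25 genes on each side of Sox10, on heterozygous cells in wild-type replicate 2, on a shift of that sample and on its copies of chromosome 6, were chosen only after the results were seen. Among the 14668 brighter genes, 2 of 217 gene families with a shared name stem passed a test for a higher share of genes past 2-fold than in the other brighter genes. In the Hoxb cluster, whose transcription factors mark position along the body axis, 6 of 8 brighter members were past 2-fold (75% against 5.2% of the other brighter genes, Fisher's exact test, 1-sided, adjusted p 0.000107). Hoxb2 (1.32), Hoxb3 (1.08) and Hoxb4 (1.22) were higher and Hoxb5 (−1.20), Hoxb6 (−1.85) and Hoxb7 (−1.43) lower in the heterozygous line. Cyclic nucleotide phosphodiesterases, which break down cAMP and cGMP, had 8 of 21 brighter members past 2-fold (38.1% against 5.1%, adjusted p 0.000617). Besides Pde7b, Pde3a (2.31), Pde8b (1.91), Pde7a (1.70), Pde2a (1.08) and Pde4b (1.04) were higher, and Pde11a (−2.03) and Pde5a (−1.55) lower. Members of a family are not independent of each other.

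Among the genes ranked after the 12 largest differences each way, Fstl1, a secreted glycoprotein gene, was higher by 4.29 (SE 0.10), the thrombin receptor gene F2r by 4.12 (SE 0.16) and the actin-linked adaptor gene Sorbs2 by 4.11 (SE 0.10). The transcription factor genes Fli1 (3.91, SE 0.08) and Foxf1 (3.54, SE 0.15) and the retinaldehyde dehydrogenase gene Aldh1a1 (3.71, SE 0.34) were higher too. On the other side stood Moxd1 (−4.28, SE 0.10), the imprinted gene Peg3 (−3.94, SE 0.16), the myelin protein gene Pmp2 (−3.25, SE 0.11) and Irf4, a pigmentation regulator gene (−3.25, SE 0.22).

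Acta2, Cald1, Dcn and Fbln5 were among the genes with the largest rises in the heterozygous line. Smooth muscle cells in which all markers rise along with Acta2 are argued against. Myh11, Cnn1, Des, Tagln and Mylk, the other smooth muscle markers of the fixed list, had a median difference of 0.338 (SD 0.377) where Acta2 rose by 5.34. Tagln and Cnn1 did pass, however, and Cald1, outside these markers, rose by 5.13. Cells that carry only part of the marker set therefore stay open. Fibroblasts in that culture stay open: Col1a1, Col3a1, Lum, Thy1 and Pdgfra had a median difference of −0.099 (SD 0.154), with Col1a1 at 6.84 in the heterozygous line against 7.04, but these 5 leave out Pdgfrb (4.08), Fbln1 (3.18) and Col1a2 (1.24), which rose with Dcn. Of the 15 fibroblast markers 7 also belong to another list and 11 lay above the threshold for dim genes in the wild type, and of the 15 endothelial and smooth muscle markers 2 and 12. A difference in the state of the melanocytes, through Sox10, the sex of the line or its history, stays open and was not tested.

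Chromosome 6 genes were higher as a set in the heterozygous line. Regulation of part of the chromosome is argued against: all 25 windows of 100 neighbouring genes had medians of 0.152 to 0.334, above the 474 windows of the other autosomes (−0.09 to 0.09). A candidate explanation is a difference in copy number of the whole chromosome, for which the median of 0.242 over 710 genes passed a bound set before the result was seen, and the 9 pairs of arrays gave 0.119 to 0.297. Among the 172 of these genes with the lowest signal the median was −0.008, against 0.288 among the 211 with the highest, and whether the heterozygous line gained or the wild-type line lost copies cannot be read from a comparison of the lines. Expression alone does not measure copy number, and Mitf, Met and Braf lie on this chromosome.

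Wild-type replicate 2 stood apart, with 93 genes at least 2-fold higher and 168 lower than the mean of the other wild-type arrays, among them Vsnl1 (−4.62), Serpina3n (−4.53), Slc2a3 (2.98) and Atp6v0d2 (2.88). After quantile normalization 96.6% of the 261 genes stayed 2-fold. That share decides nothing about scaling of the array, since the values were already normalised between arrays. The median (5.732) and quartiles (4.393 and 7.725) of this array lay close to those of wild-type replicate 1 (5.752, 4.403 and 7.769). A second normalization could therefore move little. Heterozygous cells in the sample are argued against, since the signal of Xist, Dcn, Pde7b, Prkg1 and Fbln5 left room for at most 2.11% of them. Chromosome 6 genes were higher on this array by a median of 0.124 (highest other autosome 0.019, random gene sets −0.035 to 0.041), which may reflect more copies of chromosome 6 in part of its cells. That would not by itself account for genes on other chromosomes. Of the 261 genes, 67.8% lay on the side of the heterozygous line. Both differences behind this share are taken from the same other wild-type arrays, which by itself raises it. The share therefore decides nothing about a shift towards that line, which stays open. Hypoxia (median 0.71), glycolysis (0.32) and cell division (0.30) genes were higher on this array, and its culture conditions were not tested.

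Of the 10 splits of the 6 arrays into groups of 3, 1 (the real one) gave 2967 genes, and the highest other gave 0, with 400 to 771 genes at an unadjusted p below 0.05 by limma; 10 splits cannot give a share under 0.1. X-linked genes passed with an odds ratio of 0.935 against autosomal ones, with an upper 95% bound of 1.145; among brighter genes it was 1.22 (0.958 to 1.54). The bound of 1.5 set beforehand against a difference in sex was wrong, since X inactivation can keep X-linked genes level. Xist (6.25) and Y-linked genes such as Uty (−4.92) differed in opposite directions, as between lines of different sex. How far other differences follow from sex stays open, since sex and genotype cannot be told apart here. The 50 genes nearest to Sox10 on each side passed with an odds ratio of 0.80 (upper 95% bound 1.503), below the 2 set beforehand for linked strain sequence across them. For the 25 nearest on each side it was 1.054 with an upper bound of 2.367. Linked sequence could alter a few of these genes without raising the share that passed, so neither bound decides the question. Linked strain sequence near Sox10 stays open.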
